A study of Mus musculus with 3 samples.

How the data were processed

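Single-cell RNA sequencing was performed on fluorescent cells sorted from the atria of adult Baf53b-Cre;lox-GFP mice, in which Cre driven by Actl6b (Baf53b), a neuronal chromatin remodelling subunit, switches on GFP in neurons. The series holds 3 libraries of the 10x Chromium 3′ V3 kit, 1 from ganglia of the anterior atrial region, 1 from the posterior region and 1 from pooled (mixed) ganglia. The labels give ages of 2 months for the mixed, 3 months for the anterior and 4 months for the posterior library, and both sexes for each. The anterior and posterior titles share a date-like prefix, so whether these ages differ as labelled is uncertain. The protocol in the labels names 10 mice, a target of 3000 to 6000 cells per sample and 30000 to 50000 reads per cell. Region is confounded with library and, as labelled, with age, and no source states whether the libraries share animals.

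The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode: the values were whole numbers, and no normalization was applied. Per the file headers, the mixed matrix was written by Cell Ranger 3.1.0 and the anterior and posterior matrices by Cell Ranger 6.1.2. Per the submitters' processing notes, Cell Ranger 7.1.0, Seurat 4.4.2 and the mm10 build were used, so the version in the notes differs from those in the headers. The mixed matrix lists 31064 features, of which 11 are added sequences (WPRE, tdTomato, eGFP and QZ1 to QZ8), and the others list 32285 features each. The difference in annotation can change single genes between the mixed library and the others. It does not enter the anterior against posterior comparison, where both libraries have the same features. Coordinates are those of GENCODE vM21 on GRCm38 (mm10), matched by Ensembl identifier, and are 1-based.

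Barcodes were kept with at least 1000 UMIs, at least 500 detected genes and at most 20% mitochondrial UMIs. Of 8361 barcodes, 7091 passed. Scrublet as implemented in scanpy 1.11.5, run per library at an expected doublet rate of 0.03, marked 21 cells (0.296%), which were removed. This is far below the expected rate, so doublets probably remain among the 7070 kept cells. An alternative removed the 3% of cells with the highest doublet scores.

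Each library was clustered alone (log counts per 10000 UMIs, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). A cluster took the class with the highest mean detection of its fixed markers. It stayed unnamed with fewer than 3 markers detected in at least 25% of its cells. It also stayed unnamed with a median UMI count under the library's divided by 3 and none of the class's markers among its 10 leading genes. Leading genes were ranked by fold (with 10 CPM added) among genes with at least 20 UMIs and detection in at least 25% of the cluster's cells. They were taken against cells of other classes and against all other cells. A cluster with more leading markers of another class against the first reference, or with at least 2 and more than its own against the second, lost its name. Neuron clusters set apart in this way by satellite glia or Schwann cell markers are called neurons with glial genes. The markers were fixed beforehand, but this naming procedure was settled after the clusters had been seen, because neuron clusters led by Ddc or Dbh had at first stayed unnamed.

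Counts were summed over the neuron-like cells of each library and scaled to CPM (counts per 1000000). With 1 library per region there is no test of region. Log2 ratios carry a pseudocount of 1 CPM, and ratios have exact conditional Poisson 95% intervals. On simulated counts of 40 against 20 these intervals held the true ratio in 96% of 2000 draws. Shares of cells have exact Clopper-Pearson 95% intervals. All these intervals cover counting error only. Shares of cells with a UMI were computed after each cell was thinned to 2000 UMIs, leaving out shallower cells, beside the share in glia-like cells as background.

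Anterior and posterior sums were compared gene by gene. The genes named were the 12 highest and the 12 lowest by log2 ratio with at least 50 CPM in the higher library, a UMI in at least 10% of its neuron-like cells and at least as much CPM there as in that library's other cells. Mitochondrial, ribosomal protein, haemoglobin, Xist, Tsix and Y-linked genes were left out. Of each gene list, up to 4 members were named: the 2 highest and the 2 lowest with at least 10 CPM. Actl6b, Npy, Ddah1, Chat, Th, Dbh and Nos1 were named in every library. The lists covered cholinergic transmission, catecholamine synthesis and transport, nitric oxide signalling, neuropeptides, amino acid and amine transmitters, nicotinic receptor subunits, autonomic G protein-coupled receptors, ionotropic receptors, voltage-gated sodium channels, voltage-gated calcium channels, potassium channels, the HCN, TRP, ASIC and Piezo channels, neurotrophic factor receptors, autonomic neuron transcription factors, Hox genes, axon guidance, synaptic vesicle machinery, immediate early and dissociation response genes, axon injury response genes, interferon response and MHC class I, nuclear-encoded oxidative phosphorylation, and sex-linked genes. A list's median log2 ratio over members with at least 10 CPM in the higher library was placed among the medians of 10000 random lists of the same size, matched on mean expression in 50 bins.

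Within each library, neuron-like cells in the top 25% by Npy counts per 10000 UMIs (Npy-high) were set against those in the bottom 50% (Npy-low), and likewise for Ddah1. Because most cells had no Ddah1 UMI in the mixed and anterior libraries, the Ddah1-low class held between 50.0% and 63.7% of cells. The 6 sums (2 classes in each of 3 libraries) were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr, TMM factors, library as a block, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The gene used for the split was left out. The libraries are the replicates, and where they share animals the p-values measure only the spread between these libraries. The genes named were the 10 with the largest fold in each direction among genes past the threshold, with a mean of at least 50 CPM and the same direction in each library. For each named gene, the share of its 50-base stretches in the last 500 bases of its GENCODE vM21 transcripts that also occur in another gene's transcripts was computed, a check added after the data were seen. Tested on simulated counts with 50 genes changed at each fold, the Npy test (12904 genes) found 32% of genes changed 1.5-fold, 88% at 2-fold, 94% at 3-fold and 96% at 4-fold, with 5 false calls. The Ddah1 test (12996 genes) found 30%, 84%, 94% and 96%, also with 5 false calls. The simulated counts had a single fixed dispersion and the same fold in all 3 libraries. Measured differences can vary between libraries, as for Vip in the Npy split (log2 0.65 mixed, 2.21 anterior, 3.06 posterior). These rates therefore may not hold for the measured data.

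The grouping of libraries, the filters, the tests, the markers, the gene lists, the rule for named genes and the alternative settings below were fixed before the data were examined. The settings were a stricter cell filter (2000 UMIs, 1000 genes, 10% mitochondrial UMIs), called doublets kept, a per-cell gate of at least 5 of 13 neuron markers, Leiden resolution 2, TMM factors, totals without mitochondrial, ribosomal and haemoglobin genes, means over cells, a pseudocount of 10 CPM, other list minimums (50 CPM and none), other thinning depths (1000 and 4000 UMIs and none), DESeq2 1.42.0, RLE factors, no filter on low counts, classes of 33.3% at each end, no library block, each library left out, and cells thinned to 2000 UMIs before the split. Chosen after the data were seen were the share of cells below 4 Npy counts per 10000 UMIs with its limits of 2 and 8, the same limit as a split, the inclusion of neurons with glial genes, and the removal of the top doublet scores. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used. Reads were not analysed here.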

Results

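Intrinsic cardiac neurons sit in ganglia on the atria and relay autonomic signals to the heart. The series asks how they differ between anterior and posterior atrial ganglia, with a library of pooled ganglia beside the regional ones. The 3 libraries, 1 per group, held 2829 (mixed), 2256 (anterior) and 3276 (posterior) barcodes. Their total depths were 119825307, 55329380 and 86391988 UMIs. After filtering, 2425, 2025 and 2620 cells were kept, with median UMI counts of 50984, 24993 and 18235.5 and median gene counts of 6744, 5266 and 4612. Because each region has 1 library, differences between anterior and posterior below describe these libraries and have no replicate check.

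Neurons were the most abundant class in every library. Neuron-like cells made up 64.2% of kept cells in the mixed library (95% interval 62.3 to 66.1), 64.8% in the anterior (62.7 to 66.9) and 49.5% in the posterior (47.6 to 51.4), or 1557, 1313 and 1297 cells. A further 19.8%, 9.98% and 7.29% fell in neuron clusters whose leading genes included satellite glia or Schwann cell markers such as Fabp7. They were kept out of the neuron-like class by a naming procedure settled after the clusters had been seen. Satellite glia or Schwann cell-like cells came to 90, 55 and 206 cells, and in the anterior library Atf3, Socs3 and Jun, genes of the stress response, were among their leading genes. Fibroblast-like cells came to 86, 96 and 188, and macrophage-like cells to 49, 32 and 52. Cells like chromaffin or small intensely fluorescent cells, which store catecholamines, came to 21, 16 and 21. Rgs5, a marker of the smooth muscle cell or pericyte class, led them in each library. The markers of their own class among the 10 leading genes were Chgb and Slc18a2 in the mixed and Chgb in the anterior library. Their name is therefore less certain.

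Several classes formed clusters of their own in some libraries and depended on the clustering. Epithelial cell-like (80) and lymphocyte-like (87) clusters were found in the posterior library, where 16 of the epithelial cells were led by the airway secretory genes Scgb1a1 and Scgb3a2. At the main clustering the mixed macrophage-like cluster was led also by the immunoglobulin genes Igkc and Ighm. At a finer one (Leiden resolution 2) it was not, and lymphocyte-like clusters of 22 mixed and 11 anterior cells appeared. Cardiomyocyte-like cells numbered 72 in the anterior, 28 in the posterior and 0 in the mixed library. At resolution 2 and with called doublets kept the anterior number was 30, and 42 and 36 cells led by cardiomyocyte genes formed unnamed clusters with neuron markers. Unnamed clusters held 160 anterior (7.90%) and 383 posterior cells (14.6%), of which 145 and 300 lay in single clusters with median UMI counts of 1488 and 1461. The shares describe sorted and filtered cells, not the tissue. With a per-cell gate in place of clusters, 84.8%, 82.2% and 88.5% of kept cells passed as neurons, so the lower posterior share was not seen with it. The gate also took in shallower cells. Its posterior Npy-low and Ddah1-low classes had median UMI counts of 12102 and 7162, against 57094 in posterior neuron-like cells. Whether these shallower cells are neurons was not tested, so the gate does not decide on the posterior share. With the neurons with glial genes included, the shares were 84%, 74.8% and 56.8%, the posterior one still the lowest.

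**Figure D1:**
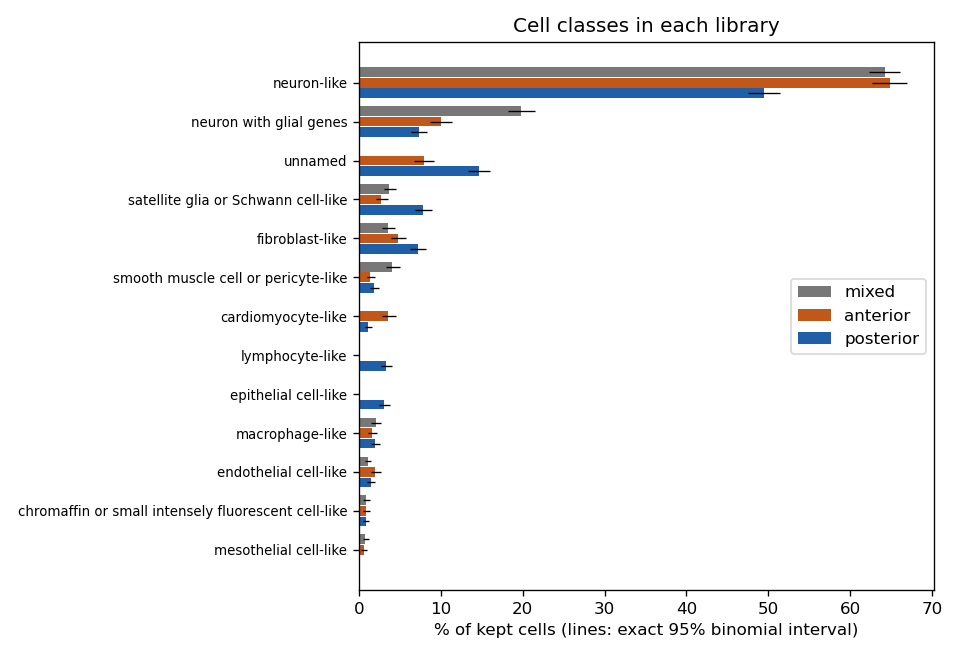
Percentage of kept cells (x axis) in each cell class (y axis) for the mixed, anterior and posterior libraries, with exact 95% binomial intervals as lines. Neuron-like cells lie at 64.2%, 64.8% and 49.5%, ahead of every other class.

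Actl6b, the gene whose Cre marked the sorted cells, was detected in neuron-like cells of every library, at 70.0 CPM (95% counting interval 68.3 to 71.8) in the mixed, 82.1 (79.5 to 84.7) in the anterior and 67.2 (65.3 to 69.2) in the posterior library. The other kept cells had 8.63, 27.0 and 32.5 CPM. Chat, which makes acetylcholine, was at 38.8, 36.9 and 46.7 CPM, and Th, the first enzyme of catecholamine synthesis, at 70.9, 87.6 and 82.9 CPM. Dbh, which converts dopamine to noradrenaline, was at 53.8 CPM (52.3 to 55.3), 69.0 (66.7 to 71.5) and 133 (131 to 136), the posterior value being the highest. Nos1, the neuronal nitric oxide synthase, was at 16.1 CPM (15.3 to 16.9), 71.3 (68.8 to 73.7) and 44.5 (43.0 to 46.1).

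At a fixed depth of 2000 UMIs per cell, most neurons had an Npy or Cartpt UMI and few had one of the other transmitter genes. Npy, the gene of neuropeptide Y, was seen in 82.6% of mixed (95% interval 80.7 to 84.5), 90.1% of anterior (88.3 to 91.7) and 68.4% of posterior neuron-like cells (65.8 to 71.0), and Cartpt in 70.4%, 73.3% and 63.9%. Glia-like cells, which should lack both, showed Npy in 29.4%, 35.3% and 38.1% and Cartpt in 2.94%, 11.8% and 21.9%. Th was seen in 10.97%, 13.5% and 12.2% of neuron-like cells, Chat in 9.55%, 9.83% and 10.7%, Dbh in 8.33%, 10.9% and 20.6%, Nos1 in 2.26%, 5.42% and 4.23% and Vip in 2.52%, 5.42% and 2.98%. The highest glia-like share was 7.84% for Th, 3.92% for Nos1 and 1.96% for Tac1 (all anterior), and 1.25% for Chat, 2.5% for Dbh and 0.625% for Vip (all posterior). Ddah1 was seen in 12.5%, 5.80% and 19.1%, against 7.35%, 15.7% (8 of 51 cells) and 7.5% of glia-like cells. Gal was seen in 2.97%, 2.40% and 4.62% with none in glia-like cells, and Tac1 in 1.48%, 1.01% and 1.64%. At this depth Sst was found in 1 mixed cell and Penk in none. Without thinning, Sst was found in 1 mixed and 1 posterior cell and Penk in 2 posterior cells. Chat was detected without thinning in 83.3%, 62.1% and 80.1% of neuron-like cells and 0%, 0% and 2.91% of glia-like cells, whose median depths were 57634, 36819 and 57094 against 3048.5, 4461 and 3614 UMIs. The thinned sets left out 8, 21 and 20 neuron-like and 22, 4 and 46 glia-like cells, with median depths before thinning of 57763, 37168 and 57648 UMIs in neuron-like and 4146.5, 4498 and 4672.5 in glia-like cells.

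Neurons formed a larger group with much Npy and a smaller one with little. Of the neuron-like cells, 10.3% in the anterior library (135 cells, 95% interval 8.69 to 12.1) had fewer than 4 Npy UMIs per 10000, against 32.4% in the posterior (420 cells, 29.8 to 35.0) and 18.0% in the mixed library (281 cells, 16.2 to 20.05). The posterior to anterior ratio of these shares was 3.15 (2.59 to 3.85). Ddah1, which breaks down a natural inhibitor of nitric oxide synthases, marked the cells with little Npy: 94.3% of them in the mixed, 69.6% in the anterior and 90.5% in the posterior library had at least 1 Ddah1 UMI per 10000. Among cells above the Npy limit this held for 5.33%, 5.35% and 14.1%. The median Ddah1 level of the cells with little Npy was 4.4, 2.26 and 2.84 per 10000 in the 3 libraries, and it was 0 above the limit. Median Fabp7 and Nppa levels were 0 in both groups.

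The limit of 4 was set after the distribution had been seen. Few cells lay near it, with 29 mixed, 52 anterior and 80 posterior cells between 2 and 8 per 10000. The cells with little Npy were not shallower, with median UMI counts of 59262, 37600 and 57917.5 against 57217, 36797.5 and 56838. In the neuron clusters with glial genes the shares were 18.8%, 11.4% and 44.5%, and the posterior to anterior ratio was 3.91 (2.44 to 6.49). These clusters come from the same libraries, so they are no second check of region.

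Among the genes higher in anterior than in posterior neurons were Npy and Nos1, by modest ratios. Of 2753 genes that met the rule for naming, the 12 with the highest anterior to posterior ratio included Islr2, Nos1, Ngb, Unc119, Tomm40, Cda, Gm10076, Nt5dc2, Stoml1, Cabp1 and Npy, with log2 ratios from 0.52 (Npy) to 0.70 (Islr2). Npy (chromosome 6, 49822710 to 49829507, plus strand) was at 4359 CPM in anterior and 3041 CPM in posterior neuron-like cells, a ratio of 1.43 (95% counting interval 1.42 to 1.44), with 4003 CPM in the mixed library. Nos1 (chromosome 5, 117781032 to 117958840, plus strand) had a ratio of 1.60 (1.52 to 1.68). It was detected without thinning in 11.1% of anterior and 11.95% of posterior neuron-like cells, and its log2 ratio was 0.67 in them and 0.85 in the other kept cells. Ngb, the oxygen-binding neuroglobin, was at 50.5 and 33.1 CPM and Tomm40, the pore of mitochondrial protein import, at 81.8 and 54.7 CPM. Gm10076 is a noncoding gene, and 69.9% of the 50-base stretches at its 3′ end also occur in the ribosomal protein gene Rpl41, so its count is uncertain. Mixed values of Nos1 (16.1 CPM) and Islr2 (23.2 CPM) lay below both regions.

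Posterior neurons carried more RNA of a noradrenaline enzyme and of several genes of the neurons with little Npy, by larger ratios. The 12 genes with the lowest anterior to posterior log2 ratio were Chodl (-1.65), Ddah1 (-1.50), Efr3a (-1.41), Serpini1 (-1.11), Olfr78 (-1.04), Dbh (-0.94), F2r (-0.77), Msi2 (-0.75), Lifr (-0.71), C78859 (-0.68), Syt4 (-0.68) and Tenm2 (-0.66). Chodl, a lectin-like membrane protein, was at 31.5 CPM in the anterior and 101 CPM in the posterior library, a posterior to anterior ratio of 3.21 (3.04 to 3.40). Ddah1 (chromosome 3, 145758675 to 145894277, plus strand) was at 47.0 (45.1 to 49.1) and 135 CPM (132 to 137), a ratio of 2.86 (2.73 to 3.00), with 101 CPM in the mixed library. Efr3a, which anchors a lipid kinase at the plasma membrane, was at 70.4 and 189 CPM. Serpini1, the secreted protease inhibitor neuroserpin, was at 59.1 and 129 CPM. Dbh (chromosome 2, 27165233 to 27183200, plus strand) had a ratio of 1.93 (1.86 to 2.01). F2r, a thrombin receptor, was at 86.3 and 147 CPM, and Lifr, a cytokine receptor, at 41.8 and 69.2 CPM. Olfr78, an olfactory receptor, was at 34.5 and 72.1 CPM. In the other kept cells the log2 ratio of Dbh was -1.34 (22.6 and 58.6 CPM). There it was -0.99 for Olfr78, -0.73 for Syt4, -0.72 for Serpini1, -0.69 for Chodl and -0.58 for F2r. It was -0.35 for Efr3a, -0.14 for C78859, -0.13 for Ddah1, -0.06 for Msi2, -0.02 for Tenm2 and 0.09 for Lifr. The differences of Dbh, Olfr78 and Syt4 were thus also seen in the other kept cells. Those cells include the chromaffin-like ones and also held neuron genes, with Npy at 1225 CPM in the anterior and 1559 CPM in the posterior library. Whether cells other than neurons differ in these genes is therefore not decided.

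The intervals cover counting error only. All 24 genes had the same direction in the neuron clusters with glial genes, which come from the same libraries and so are no second check of region. Of the 24 genes, 15 had mixed values between the anterior and the posterior ones. Within cells above the Npy limit, a median 0.722 of the log2 ratio remained, ranging from 0.192 for Npy to 1.07 for Gm10076. The fall for Npy is partly fixed, because these cells were chosen by their Npy level. Chodl kept 0.266, Efr3a 0.263, Nos1 0.381, Dbh 0.466 and Ddah1 0.677 of theirs. The libraries were otherwise close, with a median log2 ratio of -0.07 (SD across genes 0.25) and a Spearman correlation of 0.986 across 8305 genes, which are not independent replicates. Immediate early and dissociation response genes were higher in the posterior neurons (median log2 ratio -0.82), and depth and cell state differed too: 170 anterior neuron-like cells (median UMI count 8647) and 166 posterior ones (15948) lay in clusters led by the nuclear RNAs Malat1, Meg3 and Neat1 and by C78859.

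**Figure D2:**
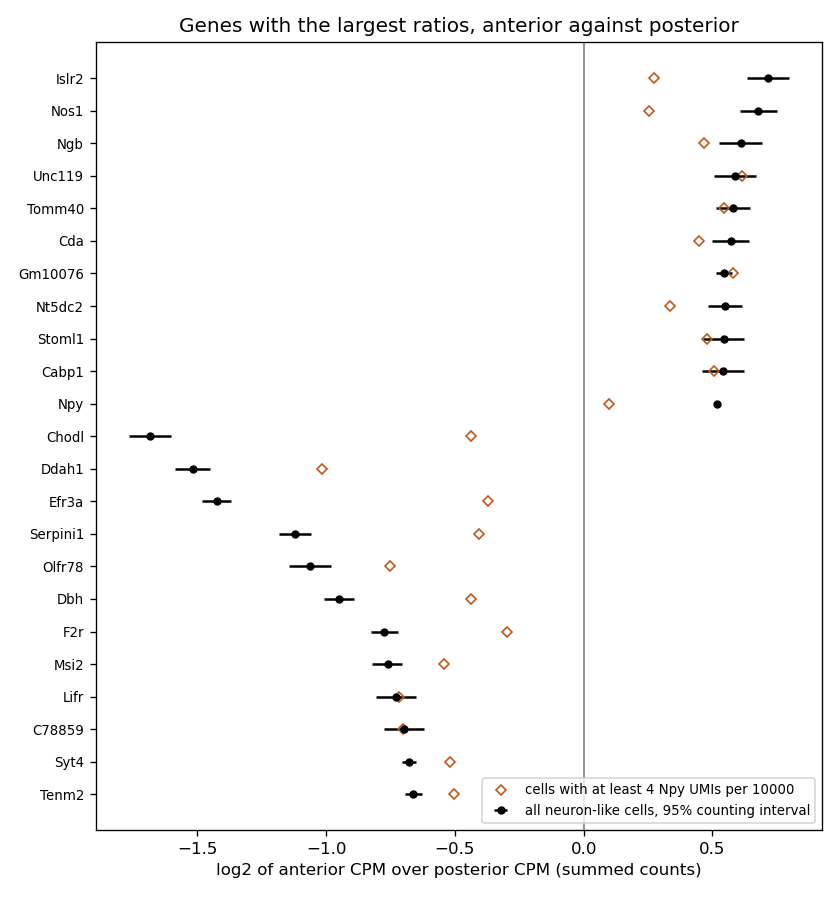
Log2 ratio of anterior over posterior CPM (x axis) for genes named by size (y axis) in all neuron-like cells, as points without pseudocount and with 95% counting intervals, and in cells with at least 4 Npy UMIs per 10000, as diamonds with a pseudocount of 1 CPM. Chodl and Efr3a move most of the way towards 0 within the Npy-rich cells, while Lifr and Unc119 do not.

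Among the gene lists, the immediate early and dissociation response genes stood furthest from random lists and were higher in posterior neurons. Their median log2 ratio was -0.82, below all 10000 random lists (percentile 0), and 6 of 17 measured members were more than 2-fold higher in the posterior library. Hspa1a, a heat shock chaperone, was at 7.55 CPM in the anterior and 29.3 CPM in the posterior library (log2 ratio -1.82), and Atf3, a stress-induced transcription factor, at 9.64 and 30.6 CPM (-1.57). The other kept cells held far more of both, with Hspa1a at 130 and 117 CPM and Atf3 at 813 and 733 CPM. Jund (0.12) and Ier3 (0.15) went the other way. The same list had a median of -0.05 in the neuron clusters with glial genes and 0.15 in the other kept cells, so it was not seen in every class. Synaptic vesicle machinery had a median of -0.16 (percentile 0.18; 18 members), with Syt4 (-0.68) and Sv2c (-0.62) at the posterior end and Stx1a (0.31) at the anterior end. Potassium channels had a median of -0.19 (percentile 0.57; 20 members), led by Kcna2 (-0.54) and Kcnq3 (-0.45). Autonomic neuron transcription factors had a median of -0.16 (percentile 1.83; 19 members). Of these, Sox11 (-0.85) and Tbx2 (-0.81) were higher in posterior neurons, and Phox2a (0.26) and Hand2 (0.21), which specify autonomic neurons, in anterior neurons. TMM factors moved the median of all genes by 0.08. With them the medians of synaptic vesicle machinery and of autonomic neuron transcription factors were -0.083 and -0.084.

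Neuropeptides were the one list above the middle 95% of random lists, with a median of 0.40 (percentile 100; 7 members) and a mean of 0.15. Npy (0.52) was higher in anterior neurons. So was Adm (0.65), at 28.9 against 18.0 CPM, but the other kept cells held 59.6 and 39.2 CPM, so its difference may come from their RNA. Within libraries, however, Adm was higher in Npy-high and lower in Ddah1-high neurons past the edgeR threshold. Part of its RNA may therefore be the neurons' own. Gal, the gene of galanin, was higher in posterior neurons at 37.4 against 13.1 CPM (-1.44). Within cells above the Npy limit the median was 0.04, and with no minimum CPM it was also 0.04, at which the list no longer stood apart. Nitric oxide signalling (median 0.14, percentile 96.2) held Nos1 at one end and Ddah1 at the other, with Ddah2 at 0.32 and Gucy1a1 at -0.26. Cholinergic transmission (0.03, percentile 68.6) had Slc5a7, the choline transporter, at -0.53, Chat at -0.33 and Ache at 0.16. Catecholamine synthesis and transport (0.07, percentile 87.5) had Dbh at -0.94 beside Gch1 at 0.17 and Ddc at 0.13. Autonomic G protein-coupled receptors (0.08, percentile 95.9) had Chrm2 at -0.58 and Adra2c at 0.30, and neurotrophic factor receptors (-0.12, percentile 17.3) had Gfra4 at 0.36 and Lifr at -0.71. At a minimum of 50 CPM both medians change sign, to -0.26 and 0.0035.

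The remaining lists lay inside the middle 95% of random lists. They were nicotinic receptor subunits (median -0.11, percentile 29.6), ionotropic receptors (-0.11, 26.6; Htr3b at -0.87), voltage-gated sodium channels (-0.18, 4.73), voltage-gated calcium channels (-0.03, 68.6), the HCN, TRP, ASIC and Piezo channels (-0.09, 47.5), Hox genes (0.09, 93.9), axon guidance (-0.10, 33.7), axon injury response genes (-0.20, 4.08), interferon response and MHC class I (-0.11, 36.3), nuclear-encoded oxidative phosphorylation (0.01, 46.3) and sex-linked genes (-0.07, 52.6; Xist at -0.54). In axon guidance Nrp2, a semaphorin receptor, was at 3.75 CPM in the anterior and 22.5 CPM in the posterior library (-2.30). The other kept cells held 34.4 and 40.7 CPM of it, and within cells above the Npy limit its log2 ratio was -0.22. List members were not required to be higher in neurons, and Kcna2, Ddah2, Jund and Ier3 also had more CPM in the other kept cells of both libraries. With TMM factors the calcium channel and sex-linked medians change sign, as does the calcium channel median at a minimum of 50 CPM. No amino acid or amine transmitter gene reached 10 CPM. Percentiles describe these 2 libraries and are no test of region.

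**Figure D3:**
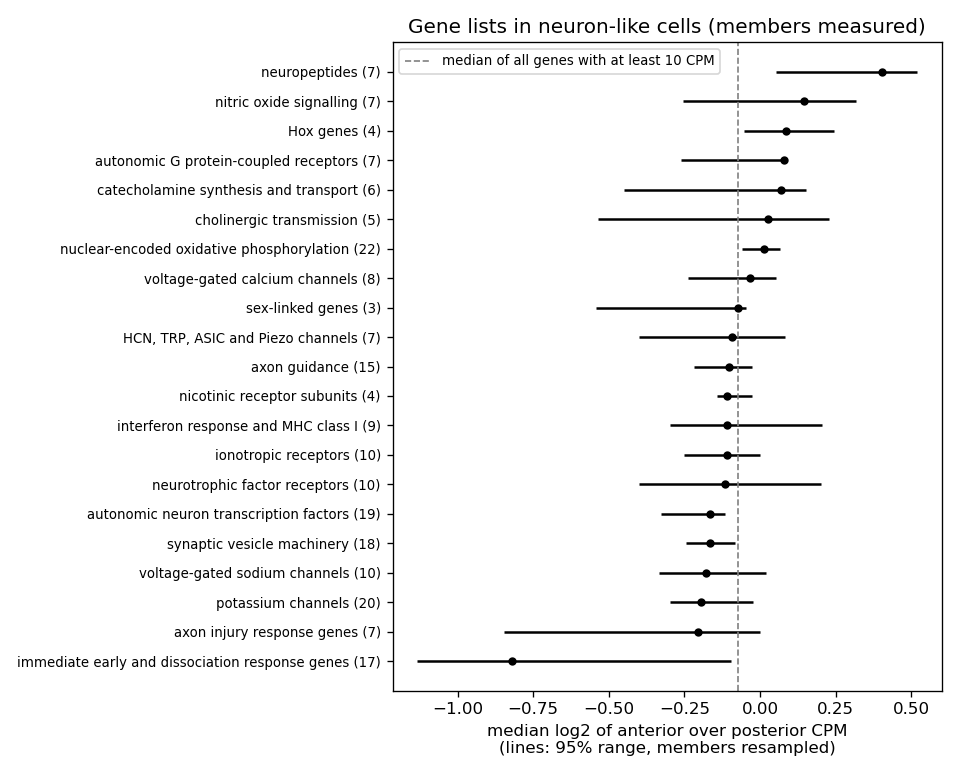
Median log2 ratio of anterior over posterior CPM (x axis) of each gene list (y axis, members measured in parentheses), with lines for the 95% range when members are resampled. The immediate early and dissociation response genes lie at -0.82 and the neuropeptides at 0.40, while the median of all genes (dashed) is -0.07.

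Npy-high neurons as a class carried more Nos1, Scg2 and Vip RNA than Npy-low neurons in each library. They also carried more of the calcium-binding S100a16, S100a4 and S100a6. Without thinning, Nos1 was detected in 6.36% of mixed, 11.1% of anterior and 11.95% of posterior neuron-like cells. Vip was detected in 4.95%, 10.3% and 9.95%, so the sums of both genes rest on a minority of cells. With the library as a block, edgeR called 1095 of 12868 genes past an adjusted p of 0.05, of which 537 were higher and 558 lower in Npy-high cells, and 1089 had the same direction in all 3 libraries. Nos1 had the largest difference of the named genes higher in Npy-high cells, at 119 ± 75.1 CPM (SD, n = 3 libraries) in Npy-high and 11.7 ± 9.55 in Npy-low cells, a log2 difference of 3.42 (SE 0.21, edgeR adjusted p = 3.21e-05). Scg2, a granin of dense core vesicles, was higher at 210 ± 24.0 against 50.5 ± 24.2 CPM and Vip, the gene of vasoactive intestinal peptide, at 161 ± 102 against 33.8 ± 13.6 CPM. S100a16 (2.07), S100a4 (1.66) and S100a6 (1.35) were higher, as were Igfbp7 (1.52), the cyclin gene Ccnd1 (1.31), Asl (1.07), an enzyme of arginine synthesis, and Plpp1 (1.02). Of the 50-base stretches at the 3′ end of S100a4, 47.4% also occur in Gm42674, so its count is less certain.

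Of the 12 genes named as higher in posterior neurons, all but Tenm2 were lower in Npy-high cells past the threshold. Ddah1 was at 11.8 ± 5.34 CPM in Npy-high and 177 ± 82.5 CPM in Npy-low cells, a log2 difference of -3.86 (SE 0.28, edgeR adjusted p = 7.78e-05). Efr3a (-1.93), Chodl (-1.69), Serpini1 (-1.16), F2r (-1.08) and Dbh (-1.08) were lower too. The others were Arpc1b (-1.39), a subunit of the actin-nucleating Arp2/3 complex, Sv2c (-1.03) and Rab3c (-0.75), both of synaptic vesicles, and Akap7 (-0.76).

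By list, nitric oxide signalling split: Nos1, Asl, Ass1 and Ddah2 were higher in Npy-high cells, Ddah1 lower, and 3 of 8 members did not pass (7 past when adjusted over the list alone). Of 10 neuropeptides tested, Scg2, Vip and Adm were higher and Tac1 (-2.62), Calcb (-2.43) and Gal (-2.32) lower (8 when adjusted over the list alone). Synaptic vesicle machinery had 1 of 18 members higher (Cplx2, 0.95) and 6 lower, among them Sv2c, Rab3c and Syt4 (11 when adjusted over the list alone). Of 23 autonomic transcription factors, 4 were higher (Hand1 at 3.74, Hand2, Gata2 and Phox2a) and 5 lower (among them Onecut2, Casz1, Tbx2 and Tbx20), with 16 past when adjusted over the list alone. Potassium channels had 1 member higher and 8 lower of 34 (15), immediate early and dissociation response genes 0 higher and 5 lower of 19 (7), and cholinergic transmission 1 lower of 6 (3), the numbers in parentheses being adjusted over the list alone. None of 22 oxidative phosphorylation, 12 calcium channel or 6 sex-linked genes passed with edgeR, over all genes or when adjusted over the list alone.

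The Npy-low class is the lower 50% of cells and reached up to 39.7, 40.1 and 23.7 Npy UMIs per 10000 in the mixed, anterior and posterior libraries, so it also holds cells above the limit of 4. Without the mixed library 242 genes were higher and 276 lower, and without the posterior library 984 were higher and 849 lower. With no library block 3 genes were higher and 2 lower, and with cells thinned to 2000 UMIs 178 and 149.

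Neurons rich in Ddah1 carried less Npy and more of several genes that were lower in Npy-high cells. With edgeR, 1437 of 12989 genes were past an adjusted p of 0.05, of which 802 were higher and 635 lower in Ddah1-high cells, and 1434 had the same direction in all 3 libraries. Npy was at 1260 ± 1153 CPM (SD, n = 3 libraries) in Ddah1-high and 5287 ± 127 CPM in Ddah1-low cells (log2 difference -2.54, SE 0.50, edgeR adjusted p = 0.0219). Scg2 (-2.23), S100a16 (-1.91), the protocadherins Pcdh7 (-1.79) and Pcdh9 (-1.46), the monoamine oxidase gene Maob (-1.67), the complexin Cplx2 (-1.60) and Eya1 (-1.51) were lower too. Chodl was higher at 172 ± 99.02 against 22.4 ± 1.51 CPM (2.76), as were Efr3a (2.20), Arpc1b (2.10), Dbh (1.60), Serpini1 (1.57), Lxn (1.42), the tetraspanin Cd63 (1.39), F2r (1.26) and Cidea (1.11). Of the 20 genes named by size in this split, 17 lost the threshold without the mixed library and 12 without the posterior library. A pseudogene, Cd63-ps, shares 31.9% of the 3′ stretches of Cd63.

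Mucl1, a small mucin-like gene, had the largest difference of the named genes but was almost limited to 2 libraries. It was at 200 CPM in Ddah1-high and 0.122 CPM in Ddah1-low cells of the mixed library, and at 110 and 1.01 CPM in the posterior library. In the anterior library it was at 0.783 CPM in Ddah1-high cells with no count in Ddah1-low cells. The fitted log2 difference was 8.20 (SE 0.47, edgeR adjusted p = 0.000292).

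By list, Ddah1-high cells had more of Gal (3.85), Calcb (3.02) and Calca (2.46) and less of Npy, Scg2 and Adm among 11 neuropeptides (6 past when adjusted over the list alone). Of 18 synaptic vesicle genes, 5 were higher (Sv2c, Rab3c, Syt4, Cplx1 and Sv2a) and 3 lower (12 when adjusted over the list alone). Of 22 oxidative phosphorylation genes 6 were higher, among them Cycs (0.38), and 0 were lower (17 when adjusted over the list alone). Autonomic transcription factors had 6 higher, led by Onecut2 (2.16) and Tbx2 (1.36), and 7 lower, led by Hand1 (-2.98), of 24 (17 when adjusted over the list alone). Immediate early and dissociation response genes had 5 higher (Socs3, Atf3, Hspb1, Dusp1 and Zfp36) and 1 lower (Egr1) of 19 (6 when adjusted over the list alone). Calcium channels, of which none passed in the Npy split, had 1 higher and 4 lower of 12 (9 when adjusted over the list alone). Of 6 sex-linked genes Tsix and Xist were lower (2 when adjusted over the list alone).

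Ddah1-high cells were deeper than Ddah1-low cells, with median UMI counts of 61099 and 51371 in the mixed, 44321 and 28768.5 in the anterior and 60085 and 54164 in the posterior library. Without the mixed library 43 genes were higher and 8 lower, without the posterior library 195 and 76, and without the anterior library 1187 and 1121. With no library block 93 were higher and 12 lower, and with cells thinned to 2000 UMIs 81 and 81. Of the 12815 genes tested in both splits, 591 were past the threshold in both, 589 of them in opposite directions. The splits use the same cells and are not independent.

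**Figure D4:**
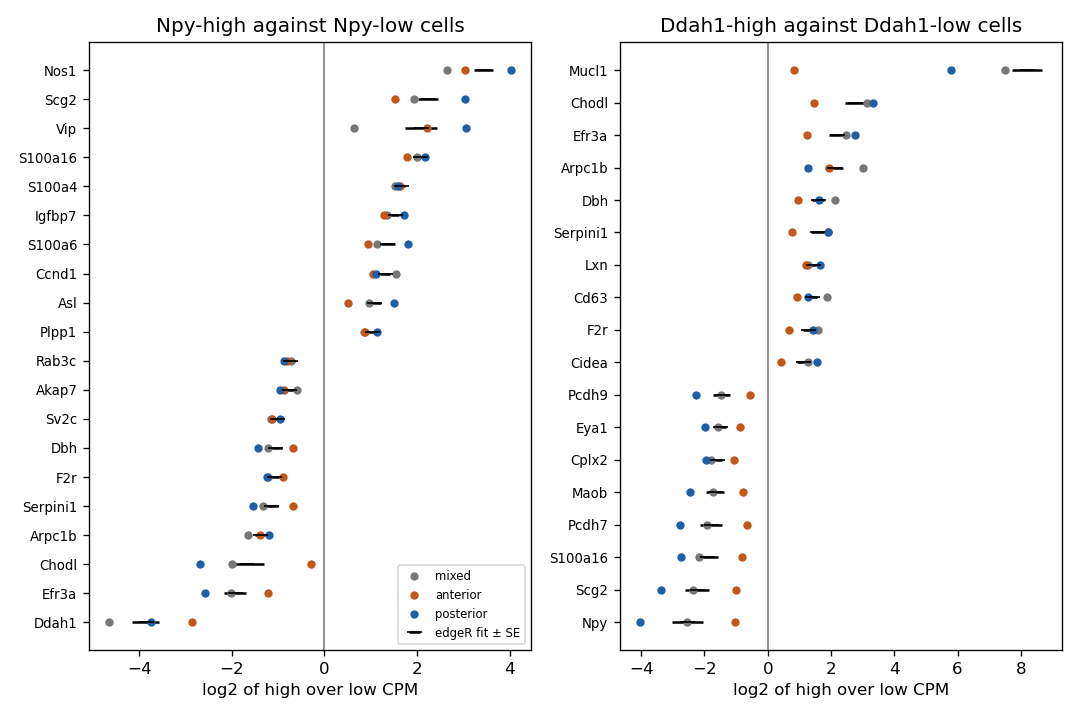
Log2 of high over low CPM (x axis) for genes named by size (y axis) in the Npy split (left) and the Ddah1 split (right), with 1 point per library and a black bar for the edgeR estimate ± SE. Points lie on the same side of 0 in all 3 libraries, which the rule for naming required. The anterior points (orange) of the Ddah1 split lie nearest to 0 for most genes. The Ddah1-high class of that library began at the lowest Ddah1 level.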

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

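The test of eGFP below was chosen after the counts had been seen. The mixed library alone lists 11 added sequences, and 1 of them had counts: eGFP, the marker used for the sort, was detected in 15.5% of its neuron-like cells (241 of 1557; 95% interval 13.7 to 17.4), in 10.8% of the neurons with glial genes and in 2 of 388 other kept cells (0.515%, 0.0625 to 1.85). Per 1000000 counts the levels were 2.90 in neuron-like and 1.52 in other cells, a ratio of 1.90 whose counting interval (0.645 to 9.30) includes 1, and the median depths were 57634 and 4602 UMIs. No explanation was tested.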

How the results depend on the processing

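The inclusion of neurons with glial genes, the removal of top doublet scores, the limits of 2, 4 and 8 Npy counts and the Npy-limit split were chosen after the data were seen. Of 1025 alternative values for 134 results, 727 stayed the same by the fixed rule, 200 moved, 98 lost the threshold and none of the values called in the first place reversed. List medians inside the middle 95% of random lists did change sign: calcium channels and sex-linked genes with TMM factors (0.049 and 0.0065), and autonomic G protein-coupled receptors (-0.26), calcium channels (0.0061) and neurotrophic factor receptors (0.0035) at a minimum of 50 CPM. The neuron-like share of kept cells under the per-cell gate was 84.8% in the mixed, 82.2% in the anterior and 88.5% in the posterior library, and with glial-gene neurons included 84.0%, 74.8% and 56.8%. Under the stricter filter the posterior share was 56.0%. The share of cells below 4 Npy counts per 10000 was 13.1% (anterior) and 39.3% (posterior) under the gate and 28.9% (posterior) under the stricter filter. It was 8.61% (anterior) with a limit of 2, and 12.6% (anterior) and 36.1% (posterior) with a limit of 8.

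The anterior over posterior log2 ratio of Npy was 0.49 under the stricter filter, 0.56 under the gate, 0.60 with TMM factors, 0.47 as a mean over cells, 0.54 with glial-gene neurons and 0.49 without the top doublet scores. That of Ddah1 was -1.43, -1.44, -1.42 and -1.60 in the first 4 of these settings and -1.34 with a pseudocount of 10 CPM. The median of neuropeptides was 0.036 with no minimum CPM, and those of autonomic transcription factors and synaptic vesicle machinery were -0.084 and -0.083 with TMM factors, which moved the median of all genes by 0.08. The largest change of a named gene under any setting was 0.42, with the stricter filter.

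Of genes higher and lower in Npy-high cells (537 and 558), 3 and 2 passed with no library block, where differences between libraries enter the residual spread, 106 and 240 under the gate, 178 and 149 with thinned cells, and 1900 and 1774 with the Npy limit as the split. DESeq2 called 345 lower, 334 of them shared. Leaving out 1 library gave 242 to 984 higher and 276 to 849 lower (lowest without the mixed, highest without the posterior library). Of genes higher and lower in Ddah1-high cells (802 and 635), 93 and 12 passed with no block, 473 and 304 with 33.3% at each end, 167 and 121 under the gate, and 81 and 81 with thinned cells. DESeq2 called 417 lower, 389 of them shared, and 1091 were lower with no filter on low counts. Leaving out 1 library gave 43 to 1187 higher and 8 to 1121 lower (lowest without the mixed, highest without the anterior library), and without the posterior library the counts were 195 and 76. Thinning also changed the classes (Ddah1-high held 6.5% to 18.8% of cells). It cut the summed counts too, as from 14046353 to 167163 in anterior Ddah1-high cells, which leaves less power to call genes. Under the gate posterior Ddah1-low cells had a median UMI count of 7162, against 54164 in the main setting. Beyond this, and apart from the missing block, the cause was not tested. Of the 20 genes named in each split, with no block 20 (Npy) and 19 (Ddah1) lost the threshold, under the gate 6 and 11, without the mixed library 0 and 17, and without the posterior library 0 and 12. Depth limits the shares of cells with a UMI, of which 77 of 108 alternative values moved.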

Other observations

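The genes in this paragraph and the next were chosen after their values were seen, as were the tests of free Npy RNA and of single libraries below. Some Hox genes, which pattern the body axis, differed between the cell classes in each split, in both directions. In edgeR, Hoxc6 (log2 difference 1.68, adjusted p = 0.0163) and Hoxc4 (0.66, 0.00196) were higher in Npy-high cells and Hoxb4 (-1.56, 0.0406) lower. In the Ddah1 split Hoxb4 (1.61, 0.0315) and Hoxb5 (1.46, 0.0234) were higher and Hoxc6 (-1.66, 0.017) and Hoxc4 (-0.97, 0.00525) lower in Ddah1-high cells. Of 10 Hox genes tested in the Npy split, 4 were higher, 1 lower and 5 not past the threshold (8 past when adjusted over the list alone), and of 10 in the Ddah1 split 2 were higher, 4 lower and 4 not past it (8). Whether the list as a whole stood out was not tested. Over all genes, without the mixed library, 242 were higher and 276 lower in Npy-high cells, and 43 and 8 in Ddah1-high cells. Most had low levels: Hoxc6 was at 1.79 ± 0.673 CPM (SD, n = 3 libraries) in Npy-high and 0.536 ± 0.175 CPM in Npy-low cells.

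Some channel and receptor genes also differed in Ddah1-high cells. Among potassium channels, Kcna5 (log2 difference 3.01, edgeR adjusted p = 0.00867) and Kcnj3 (2.59, 0.0148) were higher, and of 34 tested 6 were higher, 7 lower and 21 not past the threshold (20 past when adjusted over the list alone). The serotonin receptor gene Htr3b (2.11, 0.00197) was higher too, and of 16 ionotropic receptors 4 were higher, 3 lower and 9 not past it (8 past when adjusted over the list alone). Nrp2, a semaphorin receptor, was at 33.1 ± 27.9 CPM (SD, n = 3 libraries) in Ddah1-high and 1.99 ± 0.74 CPM in Ddah1-low cells (3.94, 0.00515), and the ephrin receptor gene Epha3 was lower (-3.30, 0.00265). Of 30 axon guidance genes 3 were higher, 7 lower and 20 not past it (15 past when adjusted over the list alone). None of these lists was tested as a whole. Without the mixed library 43 genes were higher and 8 lower in Ddah1-high cells over all genes, so calls in these lists depend on that library. Separate clusters led by Vip and Nos1 held 20 mixed and 50 anterior cells, and a posterior cluster of 147 cells was led by Nos1 and Scg2; at Leiden resolution 2 clusters led by Vip and Nos1 held 48 mixed, 50 anterior and 19 posterior cells. The highest count of a single gene in a single cell was 40831 for the immunoglobulin gene Igkc (posterior) and 10808 for the airway secretory gene Scgb1a1 (mixed).

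The share of neuron-like cells below the Npy limit was higher in the posterior than in the anterior library. Thinning every cell to 2000 UMIs left a posterior to anterior ratio of 3.19 (2.60 to 3.92), the stricter filter left 2.98 (2.40 to 3.74), and a limit on Ddah1 in place of Npy gave 3.25 (2.71 to 3.91), all above the bound of 1.5 set for depth, damaged barcodes and free Npy RNA. The values after thinning and with the Ddah1 limit argue against depth and free Npy RNA as the whole cause. The stricter filter does not decide on damaged barcodes. Median neuron-like cells had 36819 (anterior) and 57094 (posterior) UMIs, with 2.62% and 2.73% mitochondrial UMIs. These lie well inside that filter, so it may leave damaged neurons in place. A difference between single libraries, or in labelled age, cannot be told apart from region, since there was 1 library per region.

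The genes named between anterior and posterior neurons may in part reflect the mix of neurons. Within cells above the Npy limit a median 0.722 of the log2 ratio remained, with Npy itself counted among the genes. This lies between the bounds of 0.25 and 0.75 set beforehand, so the median does not decide. Genes differed: Chodl kept 0.266 and Efr3a 0.263 of their log2 ratio, which goes with a part due to the mix for them. Lifr kept 1.00 and Unc119 1.07. Cells above the Npy limit still differed in mix, with 14.1% of posterior and 5.35% of anterior ones also over the Ddah1 limit. The share that remained may therefore still hold a part due to the mix. How large that part is for the genes as a set stays open. Free RNA from other cells stays open too. The median ratio of neuron-like to other cells was 2.62, below the bound of 3. The rule for naming genes asks for at least as much CPM in neurons, which partly fixes this ratio. The other cells also held neuron genes, with Npy at 1225 CPM (anterior) and 1559 CPM (posterior), which lowers it, so the ratio cannot decide. Region and labelled age were not tested apart.

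For the genes that differed between classes, the 6 sums allow 10 splits into 3 and 3, too few for a share under 0.05. In the Npy split 1 of the 10, the real one, gave as many genes (1095, against 1 in the highest other). In the Ddah1 split it was also 1 of the 10 (1437, against 0 in the highest other). Some of the 10 place both sums of a library in the same class and so ignore the pairing. With the library as a block, such splits have little power to call genes. Of the other splits that part every pair, the highest gave 0 genes for Npy and for Ddah1, but these are fewer still.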
